A study of Homo sapiens with 8 samples.

How the data were processed

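Transcripts were measured in 8 libraries of human mesenchymal stromal cells, 2 in each of 4 groups: flat or micropillar surface, in growth or osteogenic medium. The values used are raw counts per gene, deposited by the authors as 1 file of whole numbers per library over the same 35700 Ensembl identifiers. The submitters' processing notes name cutadapt 1.13, STAR, HTSeq 0.6 and DESeq2 and the genome build hg19, without their roles or order. The versions of STAR and DESeq2 and the strand setting of the counting are not given in the sources used here. Reads were not analysed here. Library totals ran from 21479176 to 44840803 counts, and 3 counts in a library corresponded to 0.0669 to 0.14 CPM (counts scaled to the library total).

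Identifiers were given symbols from the annotation at hand: 24558 from the current gene table and 77 from GENCODE release 29 alone, while 11065 had no symbol and 14 shared one. Identifiers without a symbol held 0.46% to 0.50% of the counts and were tested but not named. The annotation is on a later genome build than the counts, so it served for names, exon lengths, GC content and shared sequence, and no coordinates are given. For 317 genes that could be named, shared 50-base sequences and overlapping exons were counted: 23 shared more than 10% of their sequences with other genes, 14 overlapped another gene on the same strand and 26 on the other strand.

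Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust quasi-likelihood fit), with all 8 libraries in 1 model and 1 coefficient per group. Of the identifiers, 20931 had any count and 14276 passed the filter. TMM factors were 0.984 to 1.024, and the common biological coefficient of variation was 4.27% with 4 residual degrees of freedom per gene and 11.8 prior ones. The comparisons were pillar against flat in each medium, osteogenic against growth medium on each surface, and the interaction of surface and medium. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and, for the members of a list, also over that list alone. Log2 fold changes are given with the standard error of the fit, and CPM as the mean and SD of 2 libraries. These CPM were scaled to each library's total of tested genes times its TMM factor. The floor of 3 counts and the flat growth levels of EPCAM, CDH1, KRT5 and KRT14 were scaled to the library total alone. With 2 libraries against 2, an exact permutation test of 1 gene cannot go below 1/3, so all tests pool the spread over genes. A ratio against a group at 0 counts is given as a lower bound against a floor of 3 counts over the group, and ALOX15B with exact 95% limits of the ratio of counts.

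Named genes were chosen by a rule: the 10 highest and 10 lowest log2 fold changes of each comparison among genes past the threshold, with no overlap of CPM between groups and a mean of at least 5 CPM over the 4 libraries compared, 5 and 5 without the overlap condition for the interaction, and up to 4 members of each list with the smallest p per comparison. Genes without a symbol, XIST and Y-linked genes were left out of naming. ALPL, BGLAP, RUNX2, FN1, ZBTB16 and the markers of other cell types named for their level fell outside this rule and were chosen after their values were seen.

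The 30 gene lists covered osteoblast, adipocyte and chondrocyte differentiation, glucocorticoid response, collagens, matrix glycoproteins and proteoglycans, collagen processing and crosslinking, matrix proteases and inhibitors, YAP and TAZ targets, MRTF-SRF targets and contractile genes, integrins and focal adhesion, nuclear lamina and LINC complex, histone and chromatin modifiers, cell cycle, cytokines and NF-kB targets, interferon response, p53 targets, hypoxia response, glycolysis, unfolded protein and amino acid stress response, cholesterol synthesis, TGF-beta and BMP targets, Wnt targets and inhibitors, growth factors and secreted trophic factors, immediate early genes, mesenchymal stromal surface markers, endothelial, blood cell and epithelial markers, and mitochondrially encoded genes. Each with at least 5 tested members was compared with the other genes by camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. The comparisons, tests, threshold, lists, naming rule and alternative settings below were set before the data were examined.

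The alternative settings were relative log expression normalization, a DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 10 CPM in 2 libraries, the replicate number as an additive block, only the 4 libraries of the groups compared, camera with a correlation estimated from the residuals, and leaving out each library in turn. A block with the numbers of the pillar osteogenic libraries exchanged, and thinning all libraries to the smallest total, were added after seeing the data. The fits were tested on simulated data with 200 changed genes per comparison. For pillar against flat in growth medium, 67.3%, 65.3%, 92% and 95.9% of genes changed 1.25, 1.5, 2 and 3-fold were called, with 18 unchanged genes called of 14099 tested. For pillar against flat in osteogenic medium these were 64%, 66%, 94% and 98% (15 of 14103), for the medium on flat 58%, 72.9%, 88% and 94% (18 of 14106), for the medium on pillars 57.1%, 66%, 94% and 98% (18 of 14098) and for the interaction 28%, 66.7%, 80% and 90% (16 of 14112). Unchanged genes made up 10.2%, 8.57%, 10.4%, 10.3% and 10.9% of the calls in these 5 simulations, above the 5% that the threshold sets. The lists of called genes may therefore hold more false calls than 0.05 states. Each simulation was run once, with 200 changed genes and 1 spread per gene in all libraries. The size of these shares may thus not carry over to the data. In a simulated shift of the cell cycle list by -0.4, camera called that list and 0 of the others. Genes were drawn independently there, so the simulation could not show false list calls that come from correlation between genes. The correlation estimated from the residuals rests on 4 residual degrees of freedom per gene. A list that did not pass with it is thus not shown to be unchanged.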

Results

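Gene expression was measured by mRNA sequencing in human mesenchymal stromal cells, primary multipotent cells bought from a commercial culture collection and seeded at passage 4 on substrates of a polymer that the labels call mPOC. The substrate was either flat or patterned with micropillars. The cells were kept in growth medium or moved to a commercial osteogenic induction medium, which directs such cells towards bone-forming cells. The 4 groups held 2 libraries each, numbered 1 and 2 as biological replicates in the labels, and all 8 libraries carry the label day 1. The labels place the change to osteogenic medium at 1 day after seeding and do not say how long the cells had been in it at harvest. The series title names constriction of the nucleus by microtopography as its subject, so the comparisons ask what the pillars changed in each medium, what the medium changed on each surface, and whether the pillar effect depended on the medium. Total counts of replicates 1 and 2 were 21479176 and 27451608 in the flat growth libraries and 29672358 and 44840803 in the pillar growth libraries. They were 31023481 and 38068160 in the flat osteogenic libraries and 44244298 and 25027077 in the pillar osteogenic libraries. Between 17263 and 18167 gene identifiers had at least 1 count in a library, and 14276 were tested.

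Medium separated the libraries most. The first principal component held 68.7% of the variance and placed the 4 growth libraries between -36 and -33 and the 4 osteogenic libraries between 32 and 37.3. The second component held 12.2% and placed the 4 flat libraries between 11.9 and 17.4 and the 4 pillar libraries between -21.5 and -8.1. Replicates correlated at 0.9949 to 0.9958 across genes within a group, against a lowest value of 0.9684 over all pairs of libraries. By the chi-square per degree of freedom of their counts, both pillar pairs differed more within the pair than both flat pairs. It was 7.62 and 9.82 on pillars and 2.78 and 3.29 on the flat surface, so no pair was a repeat of 1 library. The correlations did not show this order. In growth and osteogenic medium they were 0.9954 and 0.9949 on pillars and 0.9949 and 0.9958 on the flat surface. FN1, which encodes the matrix protein fibronectin, took 5.86% to 7.44% of all counts in a library, and the 10 most abundant genes together took 11.1% to 13.1%. Markers of other cell types ranged widely in level. The endothelial genes PECAM1 and CDH5 reached at most 0 and 1 count in any library, the leukocyte gene PTPRC at most 7, and the epithelial gene EPCAM at most 4. Other members of the same lists were present, with means over the libraries of 13.5 CPM for EGFL7 and 9.65 for TEK (endothelial), 9.02 for CSF1R, 6.15 for CD74 and 167 for CD68 (blood cell), and 153 for DSP and 12.1 for KRT19 (epithelial); 74.3% of the 50-base sequences of CD68 are shared with other genes. All 13 mitochondrially encoded genes of the list fixed for them were at 0 counts in every library, so that list was untestable.

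**Figure D1:**
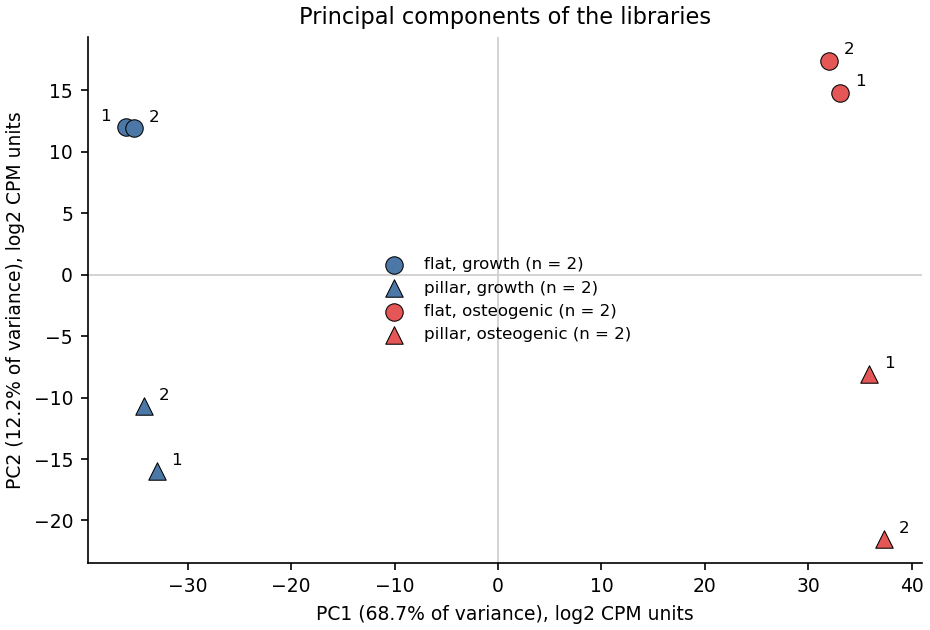
Principal components of log2 CPM (counts scaled to the library total) of the 8 libraries, with PC1 (68.7% of variance) on the x axis and PC2 (12.2%) on the y axis. Each point is 1 library, colour marks the medium, shape marks the surface and the digit is the replicate number; flat libraries lie at 11.9 or higher on PC2 and pillar libraries at -8.1 or lower.

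On pillars in growth medium, the lists of cell cycle genes, p53 targets and targets of the mechanosensitive coactivators YAP and TAZ had median log2 fold changes of -0.64, -0.24 and -0.22 and passed camera with the preset correlation (adjusted p = 0.53 for each with an estimated correlation). Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest increase was in GALNT15 (ENSG00000131386), an enzyme that starts mucin-type O-glycosylation, at 9.85 ± 1.26 CPM on pillars against 3.80 ± 0.421 on flat (mean ± SD, n = 2 each), a log2 fold change of 1.40 ± 0.13 (SE). The cytokine gene IL11 (ENSG00000095752) rose from 31.0 ± 0.314 to 65.8 ± 9.90 CPM, by 1.08 ± 0.09 on the log2 scale. DDIT4L (ENSG00000145358), an inhibitor of mTORC1 signalling, fell by 1.87 ± 0.17 on the log2 scale, from 13.9 ± 0.188 to 3.73 ± 1.03 CPM, and DKK1 (ENSG00000107984), a secreted inhibitor of Wnt signalling, fell from 138 ± 7.4 to 63.0 ± 6.66 CPM, to 0.457 of its flat level by the fit. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1184 genes changed, 474 upward and 710 downward; 10 rose and 38 fell at least 2-fold, and 3120 had an unadjusted p below the threshold. The adjusted p was 1.15e-05 for GALNT15, 1.38e-05 for IL11, 2.57e-05 for DDIT4L and 6.73e-06 for DKK1. The labels do not say whether replicates were separate cultures, so these p-values measure the spread between libraries, whose source is not given. The fit shares 1 spread per gene over the 4 groups, while by chi-square, though not by correlation, the pillar pairs differed more than the flat pairs. The p-values of all comparisons that include pillars may therefore understate the spread of the pillar libraries.

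Other genes among the 10 largest increases under the same limits were RASD1, a Ras-related GTPase induced by glucocorticoids, with a log2 fold change of 1.01 ± 0.12, HBEGF, an EGF-family growth factor, at 0.69 ± 0.11, the chondroitin sulfate synthesis enzyme CSGALNACT2 at 0.62 ± 0.09, GEM at 0.60 ± 0.09 and NMB at 0.58 ± 0.08. Among the 10 largest decreases were the cadherin gene CDH6, which fell by 1.16 ± 0.10, the mitotic kinesin gene KIF20A, which fell by 1.19 ± 0.17, the spindle gene DLGAP5, which fell by 1.18 ± 0.16, and the keratin gene KRT7, which fell by 1.36 ± 0.19. KRT81, a hair keratin, fell by 1.28 ± 0.11, from 82.8 ± 6.05 to 33.8 ± 3.81 CPM; 43.7% of its 50-base sequences occur in other genes, so its level is uncertain. Adjusted p-values for these genes lay between 2.27e-05 for CDH6 and 0.0022 for KRT7. Of the 20 genes with the largest changes under these limits, 14 passed the test without any 1 library. SIGLEC15 (log2 fold change 0.84 ± 0.17) did not pass without flat growth replicate 2 (adjusted p = 0.131), and IL6 (0.70 ± 0.17) did not pass without flat growth replicate 1 (0.161), replicate 2 (0.144) or pillar growth replicate 1 (0.138), nor in thinned libraries (0.107) or with only the 2 groups compared (0.086). TRIM47 (0.59 ± 0.13) and HMMR (-1.27 ± 0.23) did not pass without flat growth replicate 1 (0.0592 and 0.0552), flat growth replicate 2 (0.129 and 0.106) or pillar growth replicate 2 (0.0647 and 0.0593). KRTAP1-1 (-1.39 ± 0.26) did not pass without flat growth replicate 1 (0.0894) or replicate 2 (0.0541), nor in DESeq2 (0.0651), and PRR11 (-1.19 ± 0.25) did not pass without flat growth replicate 1 (0.0825), replicate 2 (0.152), pillar growth replicate 1 (0.203) or replicate 2 (0.164), nor with no filter on low counts (0.123). The number of changed genes was 384 without flat growth replicate 1, 294 without flat growth replicate 2 and 671 without pillar growth replicate 1.

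Of the 30 gene lists, 9 differed from the other genes in growth medium by camera with the preset correlation, and none did with an estimated correlation. The estimate rests on 4 residual degrees of freedom per gene, so failing with it does not show that a list was unchanged. The cell cycle list fell most, with a median log2 fold change of -0.64: of 25 tested members 12 fell, 21 when adjusted over the list alone, and none rose (camera adjusted p = 6.98e-20; adjusted p = 0.53 with an estimated correlation). PCNA, the sliding clamp of DNA replication, fell by 0.35 ± 0.05 on the log2 scale and the mitotic kinase gene AURKA by 0.83 ± 0.14. The mitotic checkpoint gene BUB1 fell by 0.89 ± 0.14 and CCNB2, which encodes cyclin B2, by 0.94 ± 0.16. Of these genes PCNA passed without any 1 library, and without flat growth replicate 2 the adjusted p was 0.0612 for AURKA, 0.0545 for BUB1 and 0.068 for CCNB2. Of 20 p53 targets 12 fell, 14 when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 3.5e-08; adjusted p = 0.53 with an estimated correlation). TP53I3 fell by 0.65 ± 0.06, MDM2, whose product degrades p53, by 0.40 ± 0.04 and CCNG1 by 0.24 ± 0.04. Of 23 YAP and TAZ targets 7 fell, 13 when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 7.81e-06; adjusted p = 0.53 with an estimated correlation). CCN1, a secreted matricellular protein, fell by 0.53 ± 0.06 and GGH by 0.42 ± 0.07. These 3 lists kept their camera calls without any 1 library, while the number of members that passed alone varied. Without flat growth replicate 1, flat growth replicate 2 and pillar growth replicate 1 in turn, the number that fell was 6, 1 and 4 for cell cycle, 4, 6 and 6 for p53 and 3, 2 and 3 for YAP and TAZ. Without pillar growth replicate 2 it was 6, 10 and 10. The median of YAP and TAZ targets was -0.12 without pillar growth replicate 1 and -0.31 without replicate 2.

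Matrix and contractile lists had medians from -0.12 to -0.10 in growth medium (adjusted p = 0.719 for each with an estimated correlation). Of 27 matrix glycoproteins and proteoglycans 7 fell and 1 rose, both 8 and 1 when adjusted over the list alone (median -0.12; camera adjusted p = 0.000294; adjusted p = 0.719 with an estimated correlation). EFEMP1, a fibulin, had a log2 fold change of -0.32 ± 0.06, with an adjusted p of 0.0645 without flat growth replicate 2, and the list had a median of -0.05 and 0.147 without pillar growth replicate 1, and a median of -0.26 without replicate 2. Of 21 genes of collagen processing and crosslinking 5 fell and 1 rose, 6 and 1 when adjusted over the list alone (median -0.10; camera adjusted p = 0.000712; adjusted p = 0.719 with an estimated correlation), and without pillar growth replicate 1 the adjusted p was 0.0508. LOXL3, a lysyl oxidase, fell by 0.65 ± 0.09; 19.3% of its exonic bases overlap a gene on the other strand. Of 22 collagens 3 fell, 4 when adjusted over the list alone (median -0.12; camera adjusted p = 0.0106; adjusted p = 0.719 with an estimated correlation), with 0.268 without flat growth replicate 2 (median -0.07) and 0.296 without pillar growth replicate 1 (median -0.04), and a median of -0.22 without flat growth replicate 1. Of 22 MRTF-SRF targets and contractile genes 5 fell and 1 rose, the same counts adjusted over the list alone (median -0.11; camera adjusted p = 0.00816; adjusted p = 0.719 with an estimated correlation). Without flat growth replicate 2 the adjusted p was 0.0725, and without pillar growth replicate 1 the median was 0.01 and the adjusted p 0.656. Without pillar growth replicate 2 the median was -0.22, 8 members fell and the adjusted p was 9.57e-09. The number that fell was 3, 1 and 2 without flat growth replicate 1, flat growth replicate 2 and pillar growth replicate 1. TPM1, which encodes tropomyosin 1, fell by 0.59 ± 0.07, and 21.4% of its exonic bases overlap a gene on the other strand. Of 20 interferon response genes 3 fell, 5 when adjusted over the list alone (median -0.16; camera adjusted p = 0.00373; adjusted p = 0.53 with an estimated correlation), with OAS3 at -0.65 ± 0.13 and an adjusted p of 0.117 without flat growth replicate 2. Of 19 immediate early genes 2 rose, both when adjusted over the list alone as well (median 0.23; camera adjusted p = 0.00521; adjusted p = 0.53 with an estimated correlation). The transcription factor gene KLF4 rose by 0.56 ± 0.09. The list's adjusted p was 0.41 without flat growth replicate 2 (median 0.11), 0.0602 without pillar growth replicate 1 (median 0.08) and 0.0971 with a filter of 10 CPM in 2 libraries.

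No other list passed in growth medium. Of 20 osteoblast differentiation genes 1 rose and none fell (0 when adjusted over the list alone; median -0.06; camera adjusted p = 0.618), and ALPL, the bone alkaline phosphatase, had a log2 fold change of -0.25 that did not pass. Of 17 genes of the nuclear lamina and the complex that links it to the cytoskeleton 1 rose and 1 fell (median 0.01; camera adjusted p = 0.986). Of 25 histone and chromatin modifiers 1 rose and 3 fell (median -0.06; camera adjusted p = 0.07), and of 23 integrin and focal adhesion genes 3 rose and 1 fell (median -0.03; camera adjusted p = 0.924). ITGA6, the laminin-binding integrin alpha 6, fell by 0.66 ± 0.08. Of 16 mesenchymal stromal surface markers 1 rose and 4 fell (median -0.11; camera adjusted p = 0.235), with PDGFRB, a PDGF receptor, higher by 0.55 ± 0.05. Counts that rose and fell were 4 and 1 for glucocorticoid response (camera adjusted p = 0.17), 2 and 0 for adipocyte differentiation (0.235), 0 and 2 for chondrocyte differentiation (0.235), 2 and 4 for matrix proteases and inhibitors (0.563) and 2 and 2 for cytokines and NF-kB targets (0.924). They were 4 and 0 for hypoxia response (0.0615), 1 and 2 for glycolysis (0.365), 4 and 1 for the unfolded protein and amino acid stress response (0.0615), 0 and 0 for cholesterol synthesis (0.924), 0 and 2 for TGF-beta and BMP targets (0.233) and 1 and 1 for Wnt targets and inhibitors (0.986). Growth factors and secreted trophic factors had 4 and 2 (0.196), endothelial markers 0 and 1 (0.441), blood cell markers 0 and 0 (0.854) and epithelial markers 0 and 1 (0.07). Some of these lists passed when 1 library was left out. Without pillar growth replicate 2 the adjusted p was 0.0116 for cytokines, 0.0116 for glycolysis, 0.011 for the stress response, 0.0132 for TGF-beta and BMP targets and 0.00301 for epithelial markers. Without flat growth replicate 2 it was 0.00112 for the stress response and 0.00707 for cholesterol synthesis, without flat growth replicate 1 it was 0.0422 for hypoxia response, and without pillar growth replicate 1 it was 0.011 for hypoxia response and 0.0228 for growth factors.

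On pillars in osteogenic medium, the lists of cell cycle genes, MRTF-SRF targets and contractile genes, and YAP and TAZ targets had median log2 fold changes of -0.76, -0.26 and -0.19 and passed camera with the preset correlation (adjusted p = 0.633 for each with an estimated correlation). GALNT15 rose most among genes within the same limits of level and overlap, from 12.5 ± 0.319 to 34.4 ± 0.824 CPM, a log2 fold change of 1.47 ± 0.09. RASD1 rose by 1.06 ± 0.07, from 49.7 ± 0.240 to 103 ± 4.71 CPM, and CEMIP, which takes part in hyaluronan breakdown, rose by 0.77 ± 0.05, from 763 ± 20.7 to 1300 ± 59.7 CPM. DKK1 fell by 1.68 ± 0.07, from 324 ± 3.23 to 101 ± 8.41 CPM. CCN2 (ENSG00000118523), the connective tissue growth factor, fell by 1.47 ± 0.18, from 800 ± 14.5 to 288 ± 55.7 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2099 genes changed, 866 upward and 1233 downward; 30 rose and 61 fell at least 2-fold, and 4024 had an unadjusted p below the threshold. The adjusted p was 1.09e-07 for GALNT15, 5.68e-07 for RASD1, 2.39e-07 for CEMIP, 8.49e-08 for DKK1 and 0.00676 for CCN2. The number of changed genes was 1058 without flat osteogenic replicate 1 and 791 without flat osteogenic replicate 2.

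The 20 genes with the largest changes in osteogenic medium within those limits passed the test without any 1 library and in every other alternative. Increases included the actin-binding scaffold gene MTSS1 at 0.80 ± 0.08, EFCAB13 at 0.80 ± 0.14, KCNJ15 at 0.77 ± 0.12 and TRIB3, a pseudokinase induced by amino acid stress, at 0.70 ± 0.11. TRIM47 (0.84 ± 0.10) and the antisense transcript ZMIZ1-AS1 (1.14 ± 0.21) were uncertain, since the strand setting of the counts is not given and reads from the other strand could enter. Decreases included the ubiquitin ligase gene MARCHF4 at -1.83 ± 0.15, DCLK1 at -1.34 ± 0.15, the sarcomeric gene MYPN at -1.32 ± 0.12, ANKRD1, a YAP target, at -1.32 ± 0.09, the EGF-family gene NRG1 at -1.24 ± 0.12 and THBS1, which encodes the matrix protein thrombospondin 1, at -1.20 ± 0.15. KRT7 fell by 1.33 ± 0.23, and KRT81, with its shared sequence, fell by 2.14 ± 0.17 from a mean of 17 to 3.68 CPM. Adjusted p-values for the genes of this paragraph lay between 2.91e-06 for MARCHF4 and 0.00455 for THBS1.

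In osteogenic medium 11 lists differed from the other genes by camera with the preset correlation, and none did with an estimated correlation. Of 25 cell cycle genes 23 fell, 24 when adjusted over the list alone, with a median log2 fold change of -0.76 (camera adjusted p = 6.95e-21; adjusted p = 0.633 with an estimated correlation). PCNA fell by 0.48 ± 0.05, AURKA by 0.94 ± 0.14, CDK1, the kinase that drives entry into mitosis, by 1.05 ± 0.13 and CCNB2 by 0.99 ± 0.15. The number of members that fell was 15 without flat osteogenic replicate 1 and 10 without flat osteogenic replicate 2, and the median was -0.50 without pillar osteogenic replicate 2. Of 22 MRTF-SRF targets and contractile genes 13 fell, 14 when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 2.58e-10; adjusted p = 0.633 with an estimated correlation). The number was 8 without flat osteogenic replicate 1. FHL2, a LIM-domain protein of actin filaments, fell by 0.65 ± 0.05 and TPM2, tropomyosin 2, by 0.29 ± 0.05. TPM1 fell by 0.83 ± 0.07 and the smooth muscle actin gene ACTA2 by 0.62 ± 0.09, with exon overlap on the other strand of 21.4% and 30.1%. Of 23 YAP and TAZ targets 10 fell, 15 when adjusted over the list alone, with a median of -0.19 (camera adjusted p = 2.18e-09; adjusted p = 0.633 with an estimated correlation). CCN1 fell by 0.72 ± 0.06, CRIM1 by 0.57 ± 0.05 and GGH by 0.42 ± 0.07. Of 20 p53 targets 7 fell and 1 rose, 9 and 1 when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00605; adjusted p = 0.633 with an estimated correlation). TP53I3 fell by 0.57 ± 0.06 and MDM2 by 0.30 ± 0.04, and 3 members fell without flat osteogenic replicate 2. The median was -0.08 without flat osteogenic replicate 2 and -0.08 without pillar osteogenic replicate 2. These 4 lists kept their camera calls without any 1 library.

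**Figure D2:**
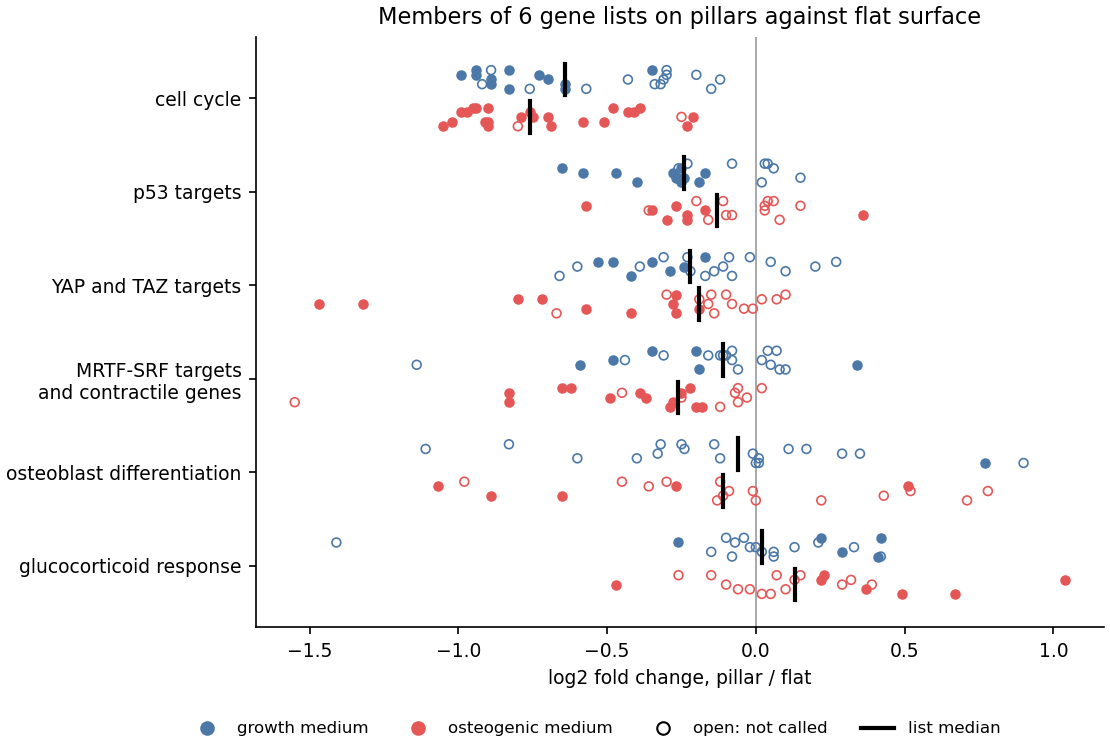
Log2 fold change of pillar over flat (x axis) for the tested members of 6 gene lists (y axis) in growth and osteogenic medium. Each point is 1 gene, filled where its adjusted p passed 0.05, and the black bar is the list median, -0.64 and -0.76 for cell cycle and -0.06 and -0.11 for osteoblast differentiation; ZBTB16, at 0 counts in growth medium, is not drawn there.

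Of 21 TGF-beta and BMP targets 4 fell and 1 rose, 7 and 1 when adjusted over the list alone (median -0.16; camera adjusted p = 0.00605; adjusted p = 0.633 with an estimated correlation), with the activin A gene INHBA at -0.32 ± 0.06. Without pillar osteogenic replicate 2 the median was -0.07 and the adjusted p 0.129, and without replicate 1 the median was -0.26. Of 21 genes of collagen processing and crosslinking 6 fell and 1 rose, 8 and 1 when adjusted over the list alone (median -0.10; camera adjusted p = 0.00683; adjusted p = 0.709 with an estimated correlation). The transglutaminase gene TGM2 fell by 0.60 ± 0.06 and the collagen lysyl hydroxylase gene PLOD2 by 0.38 ± 0.05. Of 27 matrix glycoproteins and proteoglycans 7 fell and 2 rose, the same counts adjusted over the list alone (median -0.09; camera adjusted p = 0.0166; adjusted p = 0.709 with an estimated correlation). The proteoglycan gene VCAN fell by 0.67 ± 0.10, and DCN, decorin, rose by 0.27 ± 0.05. Without pillar osteogenic replicate 2 both lists lost the call, with adjusted p of 0.484 for processing and 0.974 for glycoproteins, and the medians were 0.02 and 0.01, against -0.17 and -0.21 without replicate 1; the glycoproteins also had 0.0535 without flat osteogenic replicate 2 and 0.0542 with the stricter filter. Of 20 interferon response genes 3 fell, 4 when adjusted over the list alone (median -0.20; camera adjusted p = 0.0256; adjusted p = 0.633 with an estimated correlation), with IFI44L at -0.57 ± 0.08. Without flat osteogenic replicate 1 and pillar osteogenic replicate 1 the list's median was -0.12 and -0.07 and its adjusted p 0.0625 and 0.383, and it was 0.0534 in libraries thinned to the smallest total and 0.0542 with the stricter filter.

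Lists that were higher on pillars in osteogenic medium were the unfolded protein and amino acid stress response, cholesterol synthesis and glucocorticoid response. Of 20 stress response genes 4 rose, the same adjusted over the list alone (median 0.12; camera adjusted p = 0.00974; adjusted p = 0.709 with an estimated correlation), and the median was 0.03 without pillar osteogenic replicate 2 (adjusted p = 0.219) and 0.24 without replicate 1. TRIB3 was among them. Of 19 cholesterol synthesis genes 2 rose (median 0.10; camera adjusted p = 0.0237; adjusted p = 0.709 with an estimated correlation), with MVD at 0.33 ± 0.06; without flat osteogenic replicate 1 and pillar osteogenic replicate 2 the adjusted p was 0.0814 and 0.0854, and with the stricter filter 0.066. Of 21 glucocorticoid response genes 6 rose and 1 fell, 9 and 2 when adjusted over the list alone (median 0.13; camera adjusted p = 0.0256; adjusted p = 0.633 with an estimated correlation). TSC22D3, a glucocorticoid-induced leucine zipper protein, rose by 0.49 ± 0.06 and the kinase gene SGK1 fell by 0.47 ± 0.05; without pillar osteogenic replicate 1 the list had a median of 0.08 and an adjusted p of 0.106, and with the stricter filter 0.156.

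The osteoblast differentiation list did not pass in osteogenic medium: 1 of 20 members rose and 4 fell (median -0.11; camera adjusted p = 0.268). DLX5, a transcription factor of bone formation, fell by 0.89 ± 0.11, BMP2, a bone morphogenetic protein, rose by 0.51 ± 0.06, and ALPL had a log2 fold change of -0.45 that did not pass. COL8A1 and COL12A1 fell by 0.84 ± 0.07 and 0.44 ± 0.06, among 4 of 22 collagens that fell (median -0.04; camera adjusted p = 0.135). In the nuclear lamina list 3 rose and 3 fell (median -0.04; camera adjusted p = 0.506), with TMPO, a lamina-associated protein, at -0.55 ± 0.07. In the chromatin list 3 rose and 6 fell (median -0.06; camera adjusted p = 0.242), with the histone demethylase gene KDM6B higher by 0.57 ± 0.07, and in the integrin list 3 rose and 4 fell (median -0.08; camera adjusted p = 0.312), with ITGA6 at -0.98 ± 0.09. PDGFRB rose by 0.58 ± 0.05 among stromal surface markers, of which 2 rose and 7 fell (camera adjusted p = 0.0544). Wnt targets had 1 rise and 3 falls (0.0544), growth factors 2 and 7 (0.0996), glycolysis 1 and 5 (0.0534), proteases 3 and 5 (0.433) and cytokines 1 and 3 (0.155). Hypoxia response had 3 and 3 (0.871), immediate early genes 1 and 2 (0.871), adipocyte differentiation 2 and 0 (0.266) and chondrocyte differentiation 0 and 2 (0.764). Endothelial markers had 0 and 1 (0.871), blood cell markers 0 and 0 (0.78) and epithelial markers 0 and 1 (0.312). Without pillar osteogenic replicate 1 the adjusted p was 7.01e-06 for collagens, 0.00174 for glycolysis, 0.0162 for Wnt targets, 0.0115 for growth factors and 0.0142 for stromal surface markers. Without flat osteogenic replicate 1 it was 0.0391 for collagens, and without flat osteogenic replicate 2 it was 0.0235 for Wnt targets and 0.0473 for growth factors.

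The pillar effects in the 2 media, which share no library, mostly had the same direction. Of the 1184 genes called in growth medium, 1091 (92.1%, exact binomial 95% interval 90.5 to 93.6%) changed in the same direction in osteogenic medium, among them GALNT15, RASD1, DKK1, CDH6 and KRT7. Called upward in both were 222 genes, where independent lists would share 28.8, and called downward in both were 472, where independent lists would share 61.3; 10 genes were called in opposite directions, of which 7 rose in growth medium. Across all tested genes the fold changes correlated at 0.39, and across the genes called in growth medium at 0.79. Genes are not independent replicates, so the interval describes these genes only. Both comparisons also use 1 spread per gene from the same fit. Their calls are thus not independent, and the overlaps given for independent lists may be too low.

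Osteogenic medium raised all 21 tested genes of the glucocorticoid response list on both surfaces, and single cytokine and activin genes such as LIF and INHBA fell. FKBP5 (ENSG00000096060), a co-chaperone of the glucocorticoid receptor, rose from 18.5 ± 1.70 to 434 ± 8.54 CPM on the flat surface (n = 2 each), a log2 fold change of 4.54 ± 0.06, and from 15.6 ± 0.458 to 473 ± 5.99 on pillars, 4.93 ± 0.06. PTX3, a secreted pattern recognition protein, rose from 11.2 ± 0.841 to 311 ± 9.72 CPM on flat and from 13 ± 0.907 to 284 ± 6.73 on pillars, and F3, which encodes tissue factor, rose by 4.14 ± 0.17 and 4.54 ± 0.16 on the log2 scale. INHBA, which encodes a subunit of activin, fell by 3.47 ± 0.06 on flat, from 1090 ± 69.8 to 98.5 ± 0.268 CPM, and by 3.91 ± 0.06 on pillars. LIF, an IL-6 family cytokine, fell by 3.73 ± 0.18 and 3.98 ± 0.18. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5276 genes changed on the flat surface, 2512 upward and 2764 downward, and 973 of them at least 2-fold. On pillars 5783 changed, 2781 upward and 3002 downward, and 998 at least 2-fold. Unadjusted p-values passed for 6442 and 6824 genes. The adjusted p was 1.06e-17 for FKBP5 and PTX3 and 4.99e-16 for INHBA on flat, and 3.28e-18, 1.14e-17 and 1.38e-16 on pillars.

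ALOX15B, a lipoxygenase, had 3852 counts in the flat osteogenic libraries and 2 in the flat growth libraries, a ratio per total of 1360 with an exact 95% interval of 377 to 11300. It had 4298 and 0 counts on pillars, with an exact 95% lower limit of 1250 on the ratio; these limits cover counting error only. On the flat surface increases also included AOX1 at 3.84 ± 0.09, PPP2R2C at 3.29 ± 0.11, GCLC, a subunit of the enzyme that limits glutathione synthesis, at 3.22 ± 0.09, METTL7A at 3.14 ± 0.11 and MIOS at 3.08 ± 0.05. Increases on pillars also included the transporter gene ABCA6 at 5.03 ± 0.21, CYP19A1, the aromatase that makes oestrogens, at 4.29 ± 0.19 and FPR1 at 3.24 ± 0.07. The keratin gene KRT19 fell by 4.97 ± 0.19 on flat and 4.19 ± 0.19 on pillars, and on flat MYBPH changed by -4.91 ± 0.21, CYP24A1, which inactivates vitamin D, by -3.87 ± 0.18 and ADAMTS14 by -2.98 ± 0.10. On pillars IL11 fell by 3.07 ± 0.11 and PTGS2, the inducible prostaglandin synthase, by 3.06 ± 0.22. Adjusted p-values for the genes of this paragraph lay between 2.43e-16 for MIOS and 2.32e-06 for PTGS2. The 20 largest changes on each surface among genes with a mean of at least 5 CPM and no overlap between groups passed the test without any 1 library and in every other alternative.

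All 21 glucocorticoid response genes rose on the flat surface, 21 when adjusted over the list alone, with a median log2 fold change of 2.48 (camera adjusted p = 2.29e-25; adjusted p = 0.0344 with an estimated correlation). On pillars all 21 rose as well, 21 when adjusted over the list alone, with a median of 2.43 (camera adjusted p = 1.6e-24; adjusted p = 0.0337 with an estimated correlation). GLUL, glutamine synthetase, rose by 2.26 ± 0.05 and 2.13 ± 0.05. The transcription factor gene ZBTB16 had 107 counts in the flat osteogenic and 123 in the pillar osteogenic libraries and 0 in growth medium, at least 25.3-fold and 44.1-fold higher against the floor of 3 counts over the group; with ZBTB16 at that bound the medians were 2.48 and 2.43. Of 19 cholesterol synthesis genes 16 rose on flat and 17 on pillars, 17 and 19 when adjusted over the list alone. They had medians of 0.50 and 0.59 (camera adjusted p = 3.28e-09 and 1.27e-10; adjusted p = 0.567 and 0.524 with an estimated correlation). SQLE rose by 0.89 ± 0.07 and 1.02 ± 0.07.

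Of 25 growth factors and secreted trophic factors 14 fell and 4 rose on flat and 17 fell and 3 rose on pillars, 16 and 5 and then 17 and 3 when adjusted over the list alone. Their medians were -0.44 and -0.57 (camera adjusted p = 0.00362 and 0.000121; adjusted p = 0.67 and 0.524 with an estimated correlation). VEGFA, the vascular growth factor, fell by 1.71 ± 0.06 and 1.75 ± 0.06, and ANGPTL4 rose by 2.61 ± 0.07 and 2.42 ± 0.07. Of 19 matrix proteases and inhibitors 10 fell and 3 rose on flat and 11 fell and 3 rose on pillars, the same adjusted over the list alone, with a median of -0.18 on both (camera adjusted p = 0.00362 and 0.00281; adjusted p = 0.567 and 0.524 with an estimated correlation). On pillars the median was -0.28 without pillar growth replicate 2 and -0.32 without pillar osteogenic replicate 2. ADAMTS1 fell by 1.97 ± 0.05 and 1.89 ± 0.05. Of 6 epithelial markers 3 fell on flat and 4 on pillars, 6 and 4 when adjusted over the list alone (medians -1.31 and -1.34; camera adjusted p = 0.00636 and 0.00633; adjusted p = 0.567 and 0.524 with an estimated correlation), and on pillars the adjusted p was 0.0616 with no filter on low counts. CLDN4, a tight junction protein, fell by 2.06 ± 0.22 and 2.34 ± 0.22. On pillars 8 of 15 hypoxia response genes fell and 2 rose, the same adjusted over the list alone (median -0.21; camera adjusted p = 0.00557; adjusted p = 0.524 with an estimated correlation), and 11 of 17 glycolysis genes fell and 1 rose, the same adjusted over the list alone (median -0.20; camera adjusted p = 0.00584; adjusted p = 0.795 with an estimated correlation). The hypoxia median was -0.36 without pillar osteogenic replicate 1 and the glycolysis median -0.13 without pillar growth replicate 2. ENO2, an enolase, fell by 2.00 ± 0.07 on pillars and HK2, a hexokinase, by 1.18 ± 0.06. On flat hypoxia response had a camera adjusted p of 0.0901 and glycolysis 0.0501.

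The osteoblast differentiation list moved both ways: 3 of 20 members rose and 4 fell on flat, and 5 rose and 6 fell on pillars (medians -0.05 and -0.12; camera adjusted p = 0.739 and 0.572). RUNX2, the master transcription factor of osteoblasts, rose by 0.38 ± 0.06 on flat and 0.37 ± 0.06 on pillars, DLX5 rose by 1.24 ± 0.12 and 0.75 ± 0.12, and BMP2 fell by 1.62 ± 0.06 and 1.27 ± 0.06. OMD, a small leucine-rich proteoglycan of bone, rose by 5.58 ± 0.51 and 4.39 ± 0.50 from levels near 0, to 3.11 and 1.44 CPM. ALPL had log2 fold changes of 0.05 and -0.15 that did not pass, and BGLAP, the osteocalcin gene, reached at most 14 counts in a library and was not tested. Among matrix genes DCN rose by 2.19 ± 0.05 and 2.40 ± 0.05 and COL12A1 by 1.01 ± 0.06 and 0.70 ± 0.06; 7 of 22 collagens rose and 3 fell on each surface (camera adjusted p = 0.278 and 0.256) and 9 of 27 matrix glycoproteins rose and 5 fell on each (0.23 and 0.256). On pillars the adjusted p was 0.0443 for collagens and 0.0198 for glycoproteins without pillar growth replicate 2, and 0.00664 and 0.00966 without pillar osteogenic replicate 2. The adipocyte gene CIDEC had 353 and 356 counts in osteogenic and 0 in growth medium, at least 83.3-fold and 128-fold higher against the floor. In its list 2 rose and 1 fell on each surface (0.601 and 0.587). Chondrocyte differentiation had 2 that rose and 2 that fell on each surface (0.924 and 0.991). Cell cycle genes had 5 and 3 that rose and none that fell (0.185 and 0.8), and on pillars the median was -0.35 without pillar osteogenic replicate 1 (0.00676) and 0.17 without replicate 2 (0.0064). The lamina gene LMNA fell by 0.49 ± 0.08 and 0.65 ± 0.08, in a list where 6 rose on each surface and 3 and 4 fell (0.403 and 0.634).

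The remaining lists had no camera call on either surface. YAP and TAZ targets had 8 that rose and 7 that fell on flat and 7 and 9 on pillars (camera adjusted p = 0.739 and 0.8), and ANKRD1 rose by 3.03 ± 0.10 on flat. MRTF-SRF targets had 6 and 5, then 5 and 11 (0.888 and 0.0992). On pillars this list passed without pillar growth replicate 1 (0.00186) and without pillar osteogenic replicate 1 (0.0205). Integrin and focal adhesion genes had 6 and 10, then 7 and 13 (0.403 and 0.251), with the fibronectin receptor gene ITGA5 higher by 1.76 ± 0.06 and 1.84 ± 0.06. Cytokines and NF-kB targets had 4 and 8, then 4 and 10 (0.185 and 0.0992); NFKBIA, an inhibitor of NF-kB, rose by 1.89 ± 0.06 and 1.94 ± 0.06, and the list passed on pillars with the replicate block (0.0404), without pillar growth replicate 1 (0.0377) and without replicate 2 (0.00183). Immediate early genes had 5 and 5, then 4 and 10 (0.86 and 0.122), with JUN at -1.46 ± 0.07 and -1.48 ± 0.07. P53 targets had 6 and 10, then 8 and 7 (0.215 and 0.8), interferon response genes 5 and 2, then 7 and 1 (0.192 and 0.103; 0.0187 on pillars without pillar osteogenic replicate 1), and chromatin modifiers 5 and 7 on both (0.86 and 0.991). Collagen processing had 5 and 7, then 6 and 8 (0.403 and 0.587), TGF-beta and BMP targets 7 and 5, then 6 and 7 (0.988 and 0.572), and Wnt targets 6 and 3, then 4 and 4 (0.365 and 0.991). The stress response list had 1 and 8, then 5 and 8 (0.241 and 0.581), stromal surface markers 4 and 8, then 4 and 9 (0.403 and 0.256), endothelial markers 1 and 2, then 2 and 2 (0.844 and 0.991) and blood cell markers 0 and 2 on both (0.184 and 0.143). PDGFRB rose by 1.00 ± 0.05 and 1.03 ± 0.05.

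**Figure D3:**
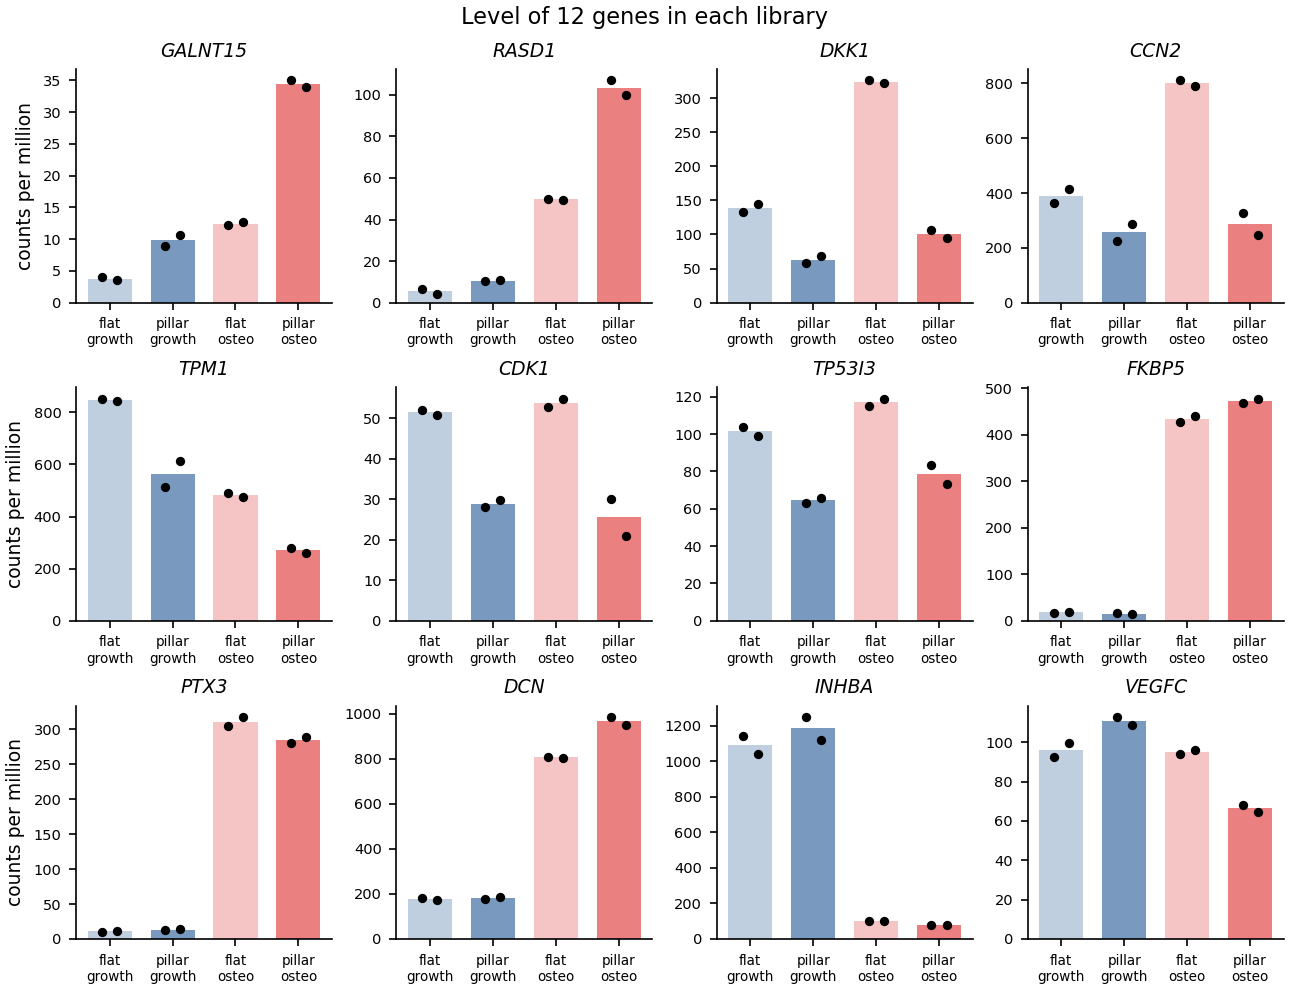
CPM (y axis, from 0) of 12 genes in the 4 groups (x axis). Bars are means of 2 libraries and points are single libraries; both DKK1 points on pillars lie below both flat points in each medium (63.0 against 138 CPM and 101 against 324 CPM as means), and FKBP5 has means of 434 and 473 CPM in osteogenic medium.

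The medium effect had the same direction on both surfaces for 5111 of the 5276 genes called on the flat surface (96.9%, exact binomial 95% interval 96.4 to 97.3%), FKBP5, PTX3, F3, INHBA and LIF among them. Called upward on both were 1879 genes, where independent lists would share 489, and called downward on both were 2135, where independent lists would share 581; 12 genes were called in opposite directions. Fold changes on the 2 surfaces correlated at 0.87 across genes, and these comparisons share no library. They do use 1 spread per gene from the same fit, so the overlaps given for independent lists may be too low.

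Few genes were called for a pillar effect that differed between media, and growth factor genes were among them. In the simulation of the interaction, 28% of the genes with the smallest simulated change were called. Small differences could thus be missed, and the count does not show how many genes differed. VEGFC (ENSG00000150630), a lymphatic vessel growth factor, had a pillar effect of 0.21 ± 0.05 in growth medium and -0.52 ± 0.05 in osteogenic medium, a difference of -0.72 ± 0.07 on the log2 scale (adjusted p = 0.000286) that passed without any 1 library. FGF7, a fibroblast growth factor, had a difference of -0.75 ± 0.10 (0.00402; 0.0593 without flat growth replicate 2), and FHL2 had -0.45 ± 0.07 (0.00607; 0.099 without flat growth replicate 1). IMPA2 rose from 4.93 to 7.20 CPM on pillars in growth medium and fell from 25.8 to 18 in osteogenic medium, a difference of -1.06 ± 0.14 (0.00298; 0.0593 without flat growth replicate 2). The interaction term in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 82 genes, 31 upward and 51 downward, and 1677 had an unadjusted p below the threshold. The count was 317 with no filter on low counts, 48 with a filter of 10 CPM in 2 libraries, 41 with a replicate block and 180 with the crossed block. For 58 of the 82 the estimated pillar effect was larger in size in osteogenic medium. For 44 the estimates had opposite signs, whether or not they were called. The pillar effect was called in both media for 26 of the 82. Leaving out 1 library moved the count of 82 to 9 without flat growth replicate 1, 5 without flat growth replicate 2, 124 without pillar growth replicate 1, 22 without flat osteogenic replicate 1, 22 without flat osteogenic replicate 2 and 141 without pillar osteogenic replicate 1.

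Among lists, the difference in pillar effect had the smallest p for MRTF-SRF targets and contractile genes, with a median of -0.18 (camera adjusted p = 1.8e-07; adjusted p = 0.832 with an estimated correlation), 2 of 22 members called downward and 3 when adjusted over the list alone. Without pillar growth replicate 2 the median was -0.07 and the adjusted p 0.00818. YAP and TAZ targets had a median of -0.08 (camera adjusted p = 0.00735; adjusted p = 0.832 with an estimated correlation), with 1 called downward and 3 when adjusted over the list alone, and the median was 0.01 without pillar growth replicate 2 (adjusted p = 0.456), -0.03 without flat growth replicate 1 and -0.15 without pillar growth replicate 1. Growth factors had a median of -0.13 (0.00764; adjusted p = 0.832 with an estimated correlation) with 3 called downward, also when adjusted over the list alone, and an adjusted p of 0.24 without pillar growth replicate 2 (median -0.04) and 0.0883 without pillar osteogenic replicate 2 (median -0.07). The cell cycle difference had a median of -0.08 that did not pass (0.0628); the adjusted p was 0.0485 without flat growth replicate 2, 0.0318 without pillar growth replicate 1, 0.01 without flat osteogenic replicate 1, and 1.27e-17 without pillar osteogenic replicate 1, where the median was -0.42.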

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

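The tests of 1 library behind the cell cycle change, of pillar growth replicate 2 behind the MRTF-SRF difference, and the thinned libraries were chosen after results were seen. The interaction term called 82 genes whose pillar effect differed between the media. Among genes with a mean of at least 5 CPM, the largest differences in pillar effect, osteogenic minus growth, were CYP26B1 1.56, DDIT4L 1.20, PTGFR 0.98, RNF144A 0.94, CORO6 0.83, MARCHF4 -1.11, IMPA2 -1.06, MYPN -0.99, IKZF2 -0.92 and ANKRD1 -0.92 on the log2 scale; each of these 10 lost its call in at least 1 fit without a library. Adjusted p without flat growth replicate 1 was 0.231 for CYP26B1, 0.237 for DDIT4L, 0.234 for PTGFR, 0.224 for RNF144A, 0.286 for CORO6, 0.108 for MARCHF4, 0.224 for MYPN, 0.209 for IKZF2 and 0.185 for ANKRD1, and without flat growth replicate 2 it was 0.0593 for IMPA2 and 0.0886 to 0.249 for the other 9. Without flat osteogenic replicate 1 it was 0.0582 (IKZF2) to 0.27 (PTGFR) and without replicate 2 0.0582 (DDIT4L) to 0.162 (IKZF2) for all but IMPA2 and ANKRD1. Without pillar growth replicate 1 it was 0.0773 for CYP26B1 and 0.0696 for PTGFR, and without replicate 2 it was 0.177 for CYP26B1, 0.104 for RNF144A, 0.109 for CORO6, 0.128 for MYPN and 0.12 for ANKRD1. Without pillar osteogenic replicate 1 it was 0.126 for DDIT4L, 0.0958 for PTGFR and 0.0792 for ANKRD1, and without replicate 2 it was 0.0768 for ANKRD1. Over all alternative settings together, DDIT4L, MYPN and PTGFR lost the call in 8 and CORO6 in 7. CYP26B1, IKZF2 and RNF144A lost it in 6, ANKRD1 in 5, MARCHF4 in 4 and IMPA2 in 1. CYP26B1, which degrades retinoic acid, had 6.40 and 2.19 CPM on flat and pillars in growth medium and 8.25 and 8.13 in osteogenic medium. ANKRD1 had 16 and 12.1, then 131 and 52.5.

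Of the lists, 8 had a pillar effect that differed between media by camera with the preset correlation, and with an estimated correlation none did (adjusted p = 0.832 for 7 of them and 0.913 for cholesterol synthesis). Median differences were -0.18 for MRTF-SRF targets and contractile genes, -0.08 for YAP and TAZ targets, -0.13 for growth factors and secreted trophic factors, -0.19 for Wnt targets and inhibitors, -0.14 for immediate early genes, -0.03 for hypoxia response, 0.08 for p53 targets and 0.09 for cholesterol synthesis. Of these, the MRTF-SRF list passed without any 1 library. YAP and TAZ targets had 0.456 without pillar growth replicate 2, and growth factors had 0.24 without pillar growth replicate 2 and 0.0883 without pillar osteogenic replicate 2. The adjusted p for p53 targets was 0.0934 without flat osteogenic replicate 1 and 0.0712 without pillar osteogenic replicate 1. For Wnt targets it was 0.0501 without flat growth replicate 1, 0.328 without pillar growth replicate 2, 0.0934 without flat osteogenic replicate 1 and 0.0883 without pillar osteogenic replicate 2. For hypoxia response it was 0.0771 without flat growth replicate 2, 0.202 without pillar growth replicate 2 and 0.0517 without pillar osteogenic replicate 2. For immediate early genes it was 0.585 without flat growth replicate 2 and 0.0924 without pillar growth replicate 1. For cholesterol synthesis it was 0.886 without pillar growth replicate 2, 0.0934 without flat osteogenic replicate 1 and 0.0883 without pillar osteogenic replicate 2, and without flat growth replicate 2 its median was -0.02 (0.962). Medians also moved: hypoxia response had -0.10, -0.08, -0.09 and -0.06 without flat growth replicates 1 and 2 and pillar growth replicates 1 and 2, -0.09 without flat osteogenic replicate 1 and -0.08 without pillar osteogenic replicate 1. Wnt targets had -0.07 without pillar growth replicate 2 and -0.10 without pillar osteogenic replicate 2, and immediate early genes had -0.23 without flat growth replicate 1 and -0.07 without flat osteogenic replicate 2. Cholesterol synthesis had 0.16 without flat growth replicate 1, 0.18 and 0.03 without pillar growth replicates 1 and 2 and 0.05 without pillar osteogenic replicate 2, and p53 targets had 0.05 without flat osteogenic replicate 1 and 0.04 without pillar osteogenic replicate 1. The MRTF-SRF, YAP and TAZ and growth factor medians were -0.07, 0.01 and -0.04 without pillar growth replicate 2.

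The MRTF-SRF list had a median difference in pillar effect of -0.18 between the media, with 2 of 22 members called and an adjusted p of 0.832 with an estimated correlation. Without pillar osteogenic replicate 2 the median difference was -0.16 (bootstrap 95% interval -0.21 to -0.08). In libraries thinned to the smallest total it was -0.14 (-0.27 to -0.11). These values argue against that library alone and against depth. The intervals resample list members, which are not independent, and do not measure the spread between libraries. Without pillar growth replicate 2 it was -0.07 (-0.12 to -0.02), so a real difference cannot be told apart from the state of that library, in which the list lay at -0.04 against -0.24 in the other pillar growth library.

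The cell cycle list had lower medians on pillars in both media by camera with the preset correlation, and the adjusted p was 0.53 in growth and 0.633 in osteogenic medium with an estimated correlation. Of 25 members 12 fell in growth medium, 1 without flat growth replicate 2, and 23 in osteogenic medium. Thinning left the list median at -0.67 in growth medium (bootstrap 95% interval -0.85 to -0.35) and -0.79 in osteogenic medium (-0.96 to -0.52). Removing the trend on exon length left -0.62 (-0.81 to -0.31) and -0.75 (-0.90 to -0.58). Removing the trend on GC content left -0.60 (-0.79 to -0.31) and -0.76 (-0.87 to -0.54). These intervals resample list members and do not measure the spread between libraries. The highest median without 1 library was -0.63 and -0.50, so no single library made it alone, but in osteogenic medium the change was larger in replicate 2: against the flat mean the pillar osteogenic libraries lay at -0.49 and -0.96. A lower proliferation on pillars is a hypothesis that these tests leave open; cell numbers were not analysed here, and differences in seeding or harvest between the surfaces were not tested.

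Summed counts of 62 keratin and keratin-associated genes, KRT8 and KRT18 left out, were lower on pillars, and KRT7 and KRT81 fell in both media, KRT81 with shared sequence; KRT19 fell by 0.63 ± 0.12 in growth medium and did not pass in osteogenic medium, and KRT8, KRT14 and KRT18 did not pass in either. Epithelial cells among the stromal cells would bring other epithelial transcripts, but EPCAM, CDH1, KRT5 and KRT14 had a median of 0.0531 CPM in the flat growth libraries, with KRT14 alone higher at 5.54 and 5.35. This argues against cells that carry EPCAM and CDH1, although other members of the epithelial list were present, with means of 153 CPM for DSP and 2.26 for CLDN4 over all libraries. Reads moving between keratin paralogs would leave their sum alone, but this sum was 0.598 to 0.742 of the flat mean in the pillar libraries. A change of KRT7 and a few other keratins in the stromal cells stays open as a hypothesis.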

How the results depend on the processing

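The crossed block and the thinned libraries were chosen after seeing the data; the other alternatives were planned. Without 1 library, called genes ranged from 294 to 874 for pillars in growth medium, 791 to 1953 in osteogenic medium and 5 to 141 for the interaction, with the lone library assumed to vary like the others. The interaction called 317 genes with no low-count filter, 48 with a filter of 10 CPM in 2 libraries, 41 with a replicate block and 180 with the crossed block; fewer genes were tested under the stricter filter, and otherwise the cause was not tested. Residuals of equal replicate number correlated at -0.35 to 0.08 between groups, so libraries of equal number did not vary together. The pillar osteogenic libraries had -0.31 with the pillar growth and -0.35 with the flat osteogenic libraries. A pattern shared between libraries of unequal number is thus not excluded, and the main model does not include it.

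The percent of pillar calls in growth medium with the same sign in osteogenic medium was 89.8 with no filter, 90.4 with the crossed block and 86.2 to 96.4 without 1 library. For medium calls on flat it was 97.6 with a replicate block, 95.9 with the crossed block, 98.1 with DESeq2 and 94.7 to 98.6 without 1 library.

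With an estimated correlation, lists called were 0 in growth medium, 0 in osteogenic medium and 0 for the interaction, and 1 (glucocorticoid response) for the medium on each surface. The stricter filter left 7 lists for pillars in osteogenic medium and 5 for the interaction. Without 1 library the numbers ran from 6 to 14 in each medium for pillars and 5 to 16 for the interaction. Medians that changed sign without 1 library included -0.35 to 0.17 for cell cycle under the medium on pillars, and for the interaction -0.13 to 0.15 for collagens, -0.08 to 0.11 for matrix glycoproteins and -0.02 to 0.18 for cholesterol synthesis. Called lists whose median crossed 0 were MRTF-SRF targets on pillars in growth medium (-0.22 to 0.01), collagen processing (-0.17 to 0.02) and matrix glycoproteins (-0.21 to 0.01) in osteogenic medium, and the YAP and TAZ interaction (-0.15 to 0.01), besides cholesterol synthesis.

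Of 640 named gene results 486 were called, of which 134 lost the call without some library and 55 in some other alternative. Depth sets a floor of 0.0669 to 0.14 CPM for 3 counts, below which a level was not resolved.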

Other observations

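The tests of 16 gene families, of which some are given, were chosen after the named genes were seen. On pillars in growth medium, families with medians near 0 also passed camera with the preset correlation. Ribosomal proteins had a median of 0.04 (camera adjusted p = 0.000421) and proteasome subunits one of 0.06 (0.000356). With an estimated correlation the adjusted p in camera was 0.209 for both, against 0.193 for centromere proteins with a median of -0.45. That estimate rests on 4 residual degrees of freedom per gene and did not separate these families. A pass with the preset correlation alone thus does not set a family apart, and failing with the estimated one does not refute it. In growth medium 13 of 33 kinesins, motors of which many act in mitosis, fell on pillars and 1 rose (median -0.45; camera adjusted p = 1.5e-06; adjusted p = 0.193 with an estimated correlation), and 9 of 21 centromere proteins fell (median -0.45; 5.8e-09; adjusted p = 0.193 with an estimated correlation). In osteogenic medium 13 of 33 kinesins fell (median -0.17; 0.000119; adjusted p = 0.317 with an estimated correlation) and 13 of 21 centromere proteins (median -0.60; 5.14e-09; adjusted p = 0.317 with an estimated correlation). Of 17 cytosolic aminoacyl tRNA synthetases, which charge tRNAs, 5 rose on pillars in growth medium (median 0.13; 1.29e-05; adjusted p = 0.193 with an estimated correlation). In osteogenic medium 2 of them rose and 1 fell (median 0.02, camera adjusted p = 0.522).

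Osteogenic medium raised 6 of 9 metallothioneins, metal-binding proteins, on each surface (medians 2.00 and 1.75; camera adjusted p = 1.75e-06 and 5.48e-05; adjusted p = 0.0918 and 0.152 with an estimated correlation). MT1E rose by 2.65 ± 0.06 on the flat surface. Of 6 aldo-keto reductases 1B and 1C, 5 rose on each surface (medians 1.98 and 2.23; 6.58e-07 and 1.09e-06; adjusted p = 0.259 and 0.371 with an estimated correlation), and 7 of 16 semaphorins fell on flat (median -0.42; 0.0354; adjusted p = 0.259 with an estimated correlation). On flat 1 semaphorin rose, and on pillars 7 fell and 2 rose (median -0.33, camera adjusted p = 0.0578).

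A smaller share of cycling cells would lower S phase and mitotic genes alike only if non-cycling cells made neither. Mitotic members had medians of -0.86 and -0.91 in growth and osteogenic medium and S phase members -0.31 and -0.43, a smaller gap of -0.47 between them (exact permutation p = 4.49e-07 and 2.24e-07 over 4457400 arrangements of 14 and 11 genes, which are not independent). S phase transcripts that non-cycling cells also make could narrow their change. The gap therefore cannot decide for or against a smaller cycling share.

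Pillars could push cells the way osteogenic medium does. Across 9771 genes the mean pillar effect and the mean medium effect correlated at 0.06, with a covariance of 0.00467 against 0.000374 from noise, so little of the pillar effect followed the medium's direction. Log2 fold changes on pillars had a rank correlation with transcript GC content of 0.03 in growth and 0.21 in osteogenic medium. The trend on GC content was removed for the cell cycle list only. Its part in the other pillar calls in osteogenic medium and in the interaction was not tested.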
